A study of Mus musculus with 4 samples.

How the data were processed

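RNA-seq was made from lung ILC2s of C57BL/6 mice, 500 cells per sample, after 6 h with IL-33 or with IL-33 plus Ang II, 2 samples per group by the titles in the labels. Per the labels' protocols, cDNA was made with a SMARTer low-input kit, amplified by PCR, fragmented enzymatically and sequenced in pairs on an Illumina NovaSeq instrument. Amplification from few cells can lose a transcript in one library and multiply it in another, which widens the spread between libraries, and no molecular identifiers are named, so PCR copies cannot be removed.

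Values are FPKM (fragments scaled to transcript length and to mapped fragments) per gene, as the authors deposited them per the file headers, with 2 decimals. The submitters' processing notes name the mm10 build, HISAT, StringTie and edgeR, with no version or role; the versions and the annotation they used are not given in the sources used here. FPKM are not counts, so count models were not used, and the depth per sample is unknown. Estimated from how often low genes are listed at 0 in one IL-33 library and not in the other, the depth is 18580000 fragments, and from the spread between these libraries it is 22430000 fragments. For simulated pairs of 20000000 fragments the estimates were 25767000 and 20500000. Both Ang II columns come from one table, and columns were matched to samples by their names. The 55401 gene models were matched by identifier to GENCODE release M21 (GRCm38, the same assembly as mm10), with 55141 found, and chromosome coordinates come from there. In all 4 libraries 37146 gene models are listed at 0.

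The IL-33 libraries were compared with each other, and the Ang II libraries likewise, before any gene was tested. Counting noise was taken at the depth estimated from detection in the IL-33 libraries, for both pairs. For genes between 1 and 32 in FPKM times transcript length in kilobases, the IL-33 libraries differed by 0.91 times that noise. The Ang II libraries differed by 14.1 times that noise. The IL-33 libraries were therefore averaged and counted as 1 sample. Above that range the IL-33 spread exceeded counting noise by 1.10 to 2.54 times. The labels do not say whether samples came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical. Here that spread comes from the 2 Ang II libraries, and the lone IL-33 sample is assumed to vary as they do; the fit has 1 residual degree of freedom. Genes with a mean of at least 1 FPKM over the 3 resulting columns (9215 genes) were tested on log2(FPKM + 1) with limma (lmFit and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and no fold is read against a group listed at 0. Gene lists, 34 in all, were tested with camera at a preset correlation of 0.01 where at least 5 members were measured (28 lists), adjusted over the lists; a member counts as higher or lower in both Ang II libraries when both lie outside both IL-33 values.

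The tests, lists, rule for named genes and most alternatives were fixed before the data were examined. By that rule the text names the 12 genes with the largest change in each direction past the adjusted threshold, with a mean of at least 5 FPKM in a group and no overlap between groups; since under 10 genes passed, they were taken among genes at an unadjusted p under 0.01 instead. It also names a fixed set of cytokine, ILC2 and angiotensin receptor genes, up to 4 members of each list described, and the 2 most abundant members of each list of another cell type or of RNA quality. Gene models without a symbol, and immunoglobulin and T cell receptor segments, were not named under the first part. The design planned the gene test over all samples with values, 2 against 2, and provided for a group with values in 1 sample only. Both IL-33 libraries have values. Counting them as 1 sample was decided after the libraries had been compared, and the fit of that provision was then used. The planned fit, with both counted as replicates, is given as an alternative. Scaling without haemoglobin genes, a minimum of 20 FPKM in every library and the settings for the similarity of the samples were added after the data had been seen.

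The gene test was checked on 20 simulated data sets of 9215 genes with 200 changed genes. The changed genes were drawn only from genes whose mean log2(FPKM + 1) lay above that of 20 FPKM, while unchanged genes were of any level. Recovery among lower genes was not simulated. The simulated IL-33 libraries shared the same deviation, drawn from the spread of the Ang II libraries, as if a single library had been measured again. With IL-33 counted as 1 sample, limma called a mean of 0 unchanged genes and recovered 0% of 4-fold and 0% of 16-fold changes at the adjusted threshold, while 7.76% of unchanged genes had an unadjusted p under 0.05, so a count of 0 passing genes says little about how many differ. With both IL-33 libraries counted as replicates of each other, 45.4% of 4-fold and 79.7% of 16-fold changes were recovered, together with a mean of 1261 unchanged genes. Alternatives covered the pseudocount, the filter, the scaling, the mean-variance trend, a replicate block, each library left out, the thresholds and other list tests. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3 with limma 3.58.1 were used.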

Results

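Group 2 innate lymphoid cells (ILC2s) are tissue-resident lymphocytes without antigen receptors that release type 2 cytokines when epithelial alarm signals reach them. ILC2s purified from the lungs of C57BL/6 mice were stimulated for 6 h with IL-33, an alarmin that activates them, or with IL-33 together with angiotensin II (Ang II), the effector peptide of the renin-angiotensin system. Each sample held 500 cells, and RNA-seq libraries were made from amplified cDNA. The series holds 4 libraries, 2 with IL-33 and 2 with IL-33 plus Ang II, and gives one FPKM value per gene and library. FPKM summed to between 394808 and 431014 per library, and between 12028 and 13401 of 55401 gene models had a value above 0. The files give no counts, so the depth behind each value is unknown.

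Before groups were compared, the libraries were set against each other. Across 9215 genes with a mean of at least 1 FPKM, log2(FPKM + 1) of the 2 IL-33 libraries correlated at Pearson r = 0.994. The 2 Ang II libraries correlated at r = 0.568, and libraries of different groups at r = 0.556 to 0.567. Spearman's rho was 0.989 for the IL-33 pair, 0.475 for the Ang II pair and 0.490 to 0.499 between groups. These correlations run across genes, which are not independent replicates. Counting noise was taken at the depth implied by detection of low genes in the IL-33 libraries. For genes between 1 and 32 in FPKM times transcript length in kilobases, the IL-33 spread was 0.91 times that noise. Between the Ang II libraries, whose own detection implies a lower depth, the spread was 14.1 times that same noise. For more abundant genes the IL-33 spread exceeded the noise, by up to 2.54 times in the 22 genes between 1024 and 2048. There it was 2.26% against 21.5% between the Ang II libraries. Among genes of middle abundance, 0.101% of 989 were listed at 0 in one IL-33 library and not in the other, against 30.5% of 1385 in the Ang II pair. In the range from 1 to 32 the IL-33 libraries differed by less than the sampling noise, and they were counted as 1 sample, with their mean as its value. In the tests IL-33 has n = 1 and Ang II n = 2.

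**Figure D1:**
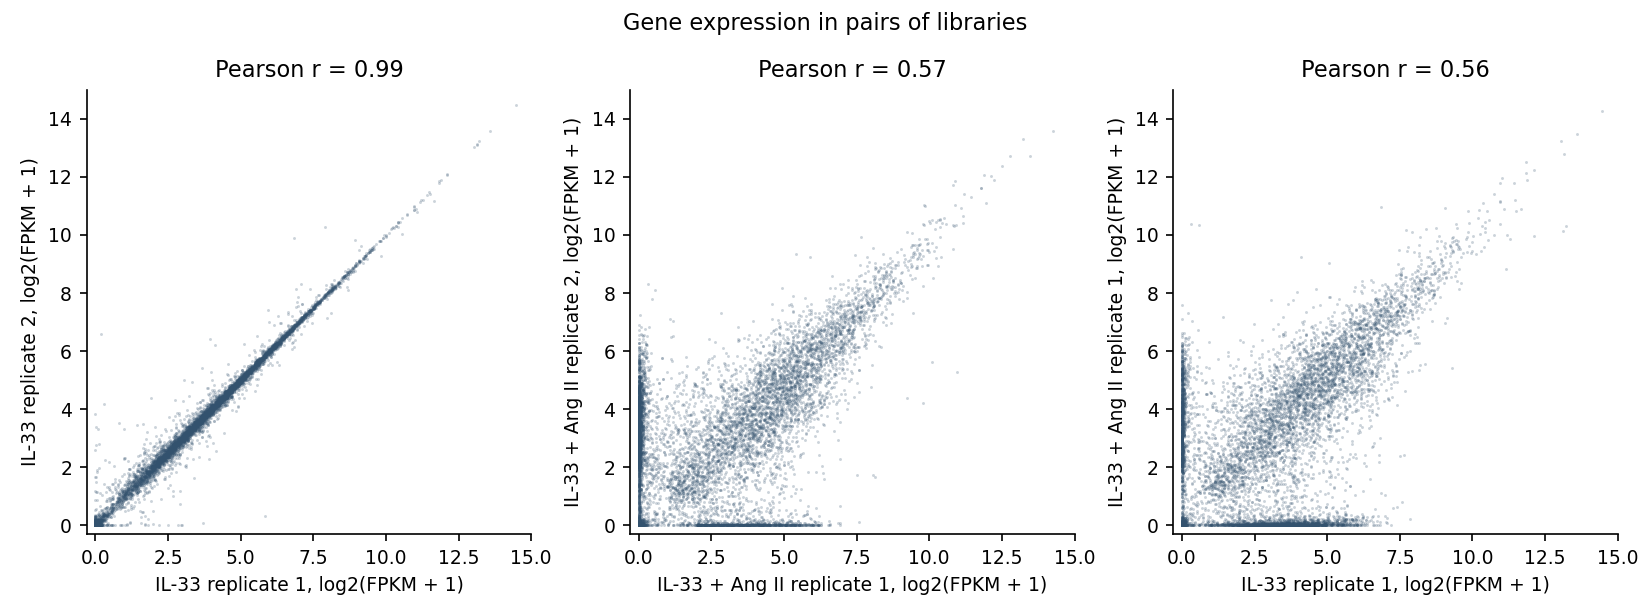
Each point is a gene (9215 genes), with log2(FPKM + 1) in one library on each axis. The left panel shows the 2 IL-33 libraries (r = 0.99), the middle panel the 2 IL-33 plus Ang II libraries (r = 0.57) and the right panel replicate 1 of each group (r = 0.56), where many genes lie along the axes because they are near 0 in one library and not in the other.

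The comparison of IL-33 plus Ang II with IL-33 alone asks, per the series title, how Ang II bears on ILC2 responses. Among cytokine genes, Il9, which encodes a cytokine that ILC2s make and respond to, was listed at a mean of 0.76 FPKM with IL-33 and at 1310 and 1483 FPKM in the Ang II libraries (log2 fold change 9.63, SE 0.23). Areg, which encodes the tissue repair factor amphiregulin, stood at 7.45 FPKM against 217 and 344 FPKM (log2 fold change 5.02, SE 0.49). Gal, the gene of the neuropeptide galanin, stood at 0.24 FPKM with IL-33 and at 1313 and 967 FPKM with Ang II (log2 fold change 9.83, SE 0.36). Neither these nor any other of the 9215 genes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg, two-sided), the smallest adjusted p being 0.174. At an unadjusted p under 0.05, 257 genes were higher and 996 lower with Ang II, 13.6% of those tested. A nominal threshold gives 460.8 genes by chance, and in simulated data of this design 7.76% of unchanged genes fell under it. These counts were 185 higher and 330 lower among genes with a mean of at least 5 FPKM, and 53 and 45 among genes with at least 20 FPKM in every library. Setting Ang II replicate 2 alone against the other samples gave a like imbalance, with 1173 genes higher and 222 lower in the lone library, and setting replicate 1 alone gave 638 and 624. With both IL-33 libraries counted as replicates, the fit planned before the libraries were compared, limma called 457 genes higher and 1090 lower at the adjusted threshold. In data simulated with the same spread, as if a single IL-33 library had been measured again, that setting called a mean of 1261 unchanged genes. That count would not hold for separate IL-33 libraries.

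Il9 lies on chromosome 13 (56479277 to 56482246, minus strand) and Gal on chromosome 19 (3409915 to 3414544, minus strand) of mm10. Among genes at an unadjusted p under 0.01, with at least 5 FPKM in a group and no overlap between groups, 9 were higher and 54 lower with Ang II, and these did not pass the adjusted threshold. Besides Il9 and Gal, the higher genes included Spp1, which encodes osteopontin (0.395 against 130 and 149 FPKM), and the kinase gene Pim3 (0.22 against 78.4 and 76.5 FPKM). The others were Trappc3 (0.15 against 85.8 and 132 FPKM), Fndc4 (0.08 against 81.1 and 67.3 FPKM), Fam122a (34.4 against 232 and 240 FPKM), Tgtp1 and Tgtp2. The interferon-inducible GTPase genes Tgtp2 (331 against 1187 and 1168 FPKM) and Tgtp1 (218 against 765 and 747 FPKM) are near-identical copies, so the authors' counting could have split reads between them. Among the 54 lower genes, the 12 named by the rule were Cmss1, Gpr155, Slc25a40, Mcoln3, Ttc32, Hinfp, Washc5, Wdr47, Spc24, Lin52, Dqx1 and Reps1. They stood between 6.00 and 6.54 FPKM with IL-33 and were listed at 0 in both Ang II libraries. Their Ang II values do not differ, so their p rests on the spread of other genes. Genes with higher IL-33 values that were at or near 0 with Ang II lay outside that p. Among them were Ccr7 (81.0 against 0.14 and 0.11 FPKM) and Tnfrsf4 (51.2 FPKM against 0 listed in both). A listed 0 in such a file need not mean absence. Of 16 genes that cells in general use, 2 (Gusb and Polr2a) were below 1 FPKM in at least 1 library. Gusb stood at 0 and 0.08 FPKM with IL-33 and at 0.02 and 2.99 FPKM with Ang II. Polr2a stood at 5.64 and 6.37 FPKM with IL-33 and at 0.05 FPKM in both Ang II libraries, close to the pattern of the 12 lower genes.

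The other cytokine and effector genes fixed for the comparison differed less, or differed between the Ang II libraries as much as between groups. Il5, which encodes the eosinophil growth factor typical of ILC2s, was listed at 0 in all 4 libraries. Il13 (chromosome 11, 53631324 to 53634702, minus strand), whose product drives mucus production, stood at 71.9 FPKM with IL-33 and at 16.3 and 0.53 FPKM with Ang II (log2 fold change -3.82, SE 2.30, adjusted p = 0.775 by limma). Il4 was at 12.9 FPKM with IL-33, at 29.4 FPKM in one Ang II library and listed at 0 in the other. Il6 was at 14.4 FPKM, with 0 listed in one Ang II library and 67.9 FPKM in the other. Csf2, the gene of GM-CSF, stood at 902 FPKM against 1819 and 731 FPKM, and Arg1, which encodes arginase 1, at 538 against 602 and 225 FPKM. Calca, which encodes calcitonin gene-related peptide, stood at 1992 FPKM with IL-33 and at 3532 and 3138 FPKM with Ang II (log2 fold change 0.74, SE 0.15, adjusted p = 0.348 by limma). Of the 20 measured genes in the list of type 2 and effector cytokines, 7 were higher and 7 lower in both Ang II libraries. In that list 0 genes passed over all genes and 1 adjusted over the list alone, and its camera adjusted p was 0.382. Nmb, the gene of neuromedin B, stood at 25.8 FPKM with IL-33 and was listed at 0 in both Ang II libraries, and Tnfsf14 stood at 23.97 FPKM against 0.17 and 0 FPKM.

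Genes that define ILC2s overlapped between groups or differed little. Il1rl1, which encodes the IL-33 receptor ST2, stood at 58.4 FPKM with IL-33 and at 43.5 and 78.7 FPKM with Ang II (log2 fold change 0.00, SE 0.60). Rora, which encodes a transcription factor that ILC2s need, was at 60.1 against 60.4 and 74.4 FPKM. Gata3, the master transcription factor of type 2 lymphocytes, was at 106 against 185 and 130 FPKM. Klrg1 stood at 293 against 283 and 449 FPKM, Icos at 353 against 264 and 383 FPKM, and Il7r at 44.3 against 37.7 and 65.7 FPKM. Of 42 measured ILC2 identity and receptor genes, 10 were higher and 13 lower in both Ang II libraries, with a median log2 fold change of -0.03 (camera adjusted p = 0.840). None of them passed, with 0 over all genes and 0 adjusted over the list alone. Among its members, Tnfrsf4, which encodes OX40, stood at 51.2 FPKM with IL-33 and was listed at 0 in both Ang II libraries. The angiotensin receptor genes Agtr1a, Agtr1b and Agtr2 were listed at 0 in all 4 libraries. Of the renin-angiotensin list, 4 genes were measured, too few for a list test, among them Atp6ap2, which encodes the prorenin receptor (107 against 56.6 and 79.9 FPKM).

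**Figure D2:**
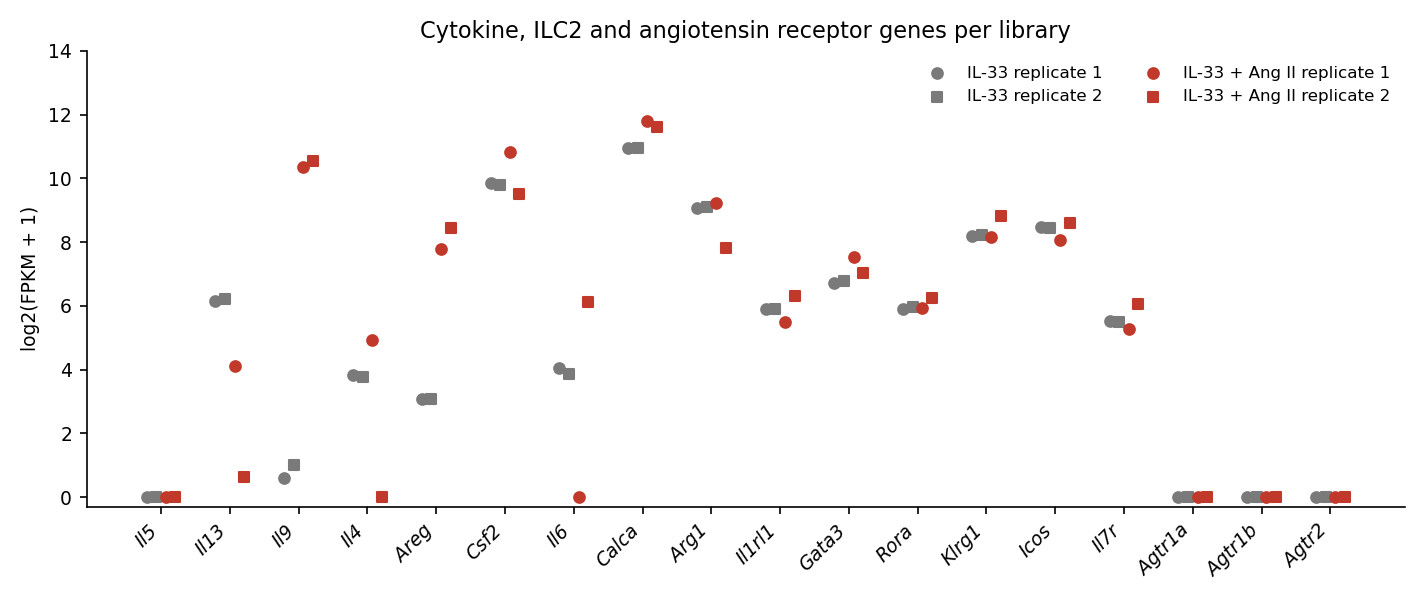
Each point is one library's log2(FPKM + 1) for a gene chosen before the data were examined, with IL-33 libraries in grey and IL-33 plus Ang II libraries in red (circles, replicate 1; squares, replicate 2). Il9 and Areg lie higher in both Ang II libraries, Il13 lies lower, the Ang II libraries part at Il4 and Il6, and Il5 and the angiotensin receptor genes are listed at 0 throughout.

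Of 34 gene lists, 28 had at least 5 measured members, and 2 passed a camera adjusted p of 0.05. The interferon response list rose with Ang II by camera with its preset correlation (adjusted p = 0.000291). It did not pass with an estimated correlation (adjusted p = 0.838 with an estimated correlation) or with the directional fry test (adjusted p = 0.465). Both of these tests rest on 1 residual degree of freedom and passed no list, so they say little about this list. Camera with its preset correlation rests on the same fit, and its pass depends on the assumed correlation of 0.01. Of the interferon list's 33 measured genes, 22 were higher and 2 lower in both Ang II libraries, with a median log2 fold change of 0.97 (0.92 and 1.13 in the separate Ang II libraries). Of all tested genes, 24.4% were higher and 33.5% lower in both, where chance alone makes a lone sample the highest or lowest of the 3 for 66.7% of genes. No member passed singly, over all genes or adjusted over the list alone. The antiviral gene Ifit1 stood at 39.5 FPKM with IL-33 and at 198 and 285 FPKM with Ang II, and Oas3 at 0.025 against 16.3 and 13.1 FPKM. Mx1 was listed at 0 in both IL-33 libraries and stood at 15.4 and 8.73 FPKM with Ang II, while Iigp1 went the other way (8.01 FPKM against 0 listed in both). A list of noncoding RNAs, named nuclear-retained and kept under RNA quality, had a median of similar size, 0.93 over 6 genes. The median was 1.18 and 0.74 in the separate Ang II libraries. Whether its members are retained in the nucleus was not tested. With 4 genes higher and 0 lower in both, the list did not pass (camera adjusted p = 0.169). Its most abundant members were Malat1 (717 against 874 and 1341 FPKM) and Gas5 (22.8 against 48.7 and 33.9 FPKM).

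Markers of T cells fell with Ang II by camera with its preset correlation (adjusted p = 0.00832). They did not pass with an estimated correlation (adjusted p = 0.838 with an estimated correlation) or with fry (adjusted p = 0.369). As for the interferon list, those 2 tests rest on 1 residual degree of freedom and say little. The pass rests on the same fit and on the assumed correlation of 0.01. Of 12 measured T cell genes, 0 were higher and 10 lower in both Ang II libraries, with a median log2 fold change of -1.71. No member passed singly, over all genes or adjusted over the list alone. Cd247 and Cd3e, which encode parts of the T cell receptor complex, stood at 26.03 against 0.05 and 0.03 FPKM and at 10.3 against 0.22 and 0.74 FPKM. Cd3d stood at 63.3 against 23.8 and 0 FPKM, and Cd4 at 6.62 FPKM against 0 listed in both. The most abundant members, the receptor constant genes Trbc2 (713 against 541 and 211 FPKM) and Trbc1 (310 against 267 and 220 FPKM), which share near-identical sequence, differed less. The list's camera adjusted p was 0.05003 among genes with a mean of at least 5 FPKM.

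Immediate early and ERK feedback genes, which respond within minutes to receptor signalling, missed the threshold (camera adjusted p = 0.0541). Of 31 measured genes, 15 were higher and 6 lower in both Ang II libraries, with a median log2 fold change of 0.54. Among genes with at least 20 FPKM in every library the median was 0.30 (camera adjusted p = 0.293). The genes that passed numbered 0 over all genes and 0 adjusted over the list alone. Nr4a1, which encodes the orphan nuclear receptor Nur77, stood at 31.6 FPKM with IL-33 and at 519 and 321 FPKM with Ang II. Myc stood at 0.035 against 22.8 and 34.5 FPKM, and Egr1 at 0.005 against 12.5 and 7.27 FPKM. Among the lower members, chosen after its values were seen, Dusp6, which encodes an ERK phosphatase, stood at 35.9 and 36.4 FPKM in the IL-33 libraries against 14.99 and 17.37 FPKM. Without IL-33 replicate 2 the list's adjusted p was 0.0327, and without IL-33 replicate 1 it was 0.0852. Cell cycle genes had a median log2 fold change of -2.10 over 17 measured genes (-2.55 and -1.03 in the separate Ang II libraries). Of the 17, 4 were higher and 9 lower in both Ang II libraries (camera adjusted p = 0.290). Of these, 0 passed over all genes and 5 adjusted over the list alone. The mitotic kinase genes Aurkb (16.4 FPKM) and Plk1 (13.5 FPKM) were listed at 0 in both Ang II libraries. The NF-kB target list had a median of -0.54 (-0.055 and -0.192 in the separate Ang II libraries). That of the chemokine list was -0.59 (-0.548 and 0.092 in the separate Ang II libraries). Camera nonetheless placed both upward relative to other genes (adjusted p = 0.840 and 0.774). It did so too for the ILC2 identity and oxidative phosphorylation lists with medians just below 0. The unfolded protein list had a median of -0.13 and a mean of 0.05, and the NFAT and calcium list a median of 0.57 and a mean of -0.08. Among NF-kB targets, Nfkbiz stood at 0.08 against 52.8 and 91.5 FPKM and Tnf at 62.4 against 0 and 27.7 FPKM. Among chemokines Ccl1 stood at 0.11 against 87.0 and 58.3 FPKM.

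**Figure D3:**
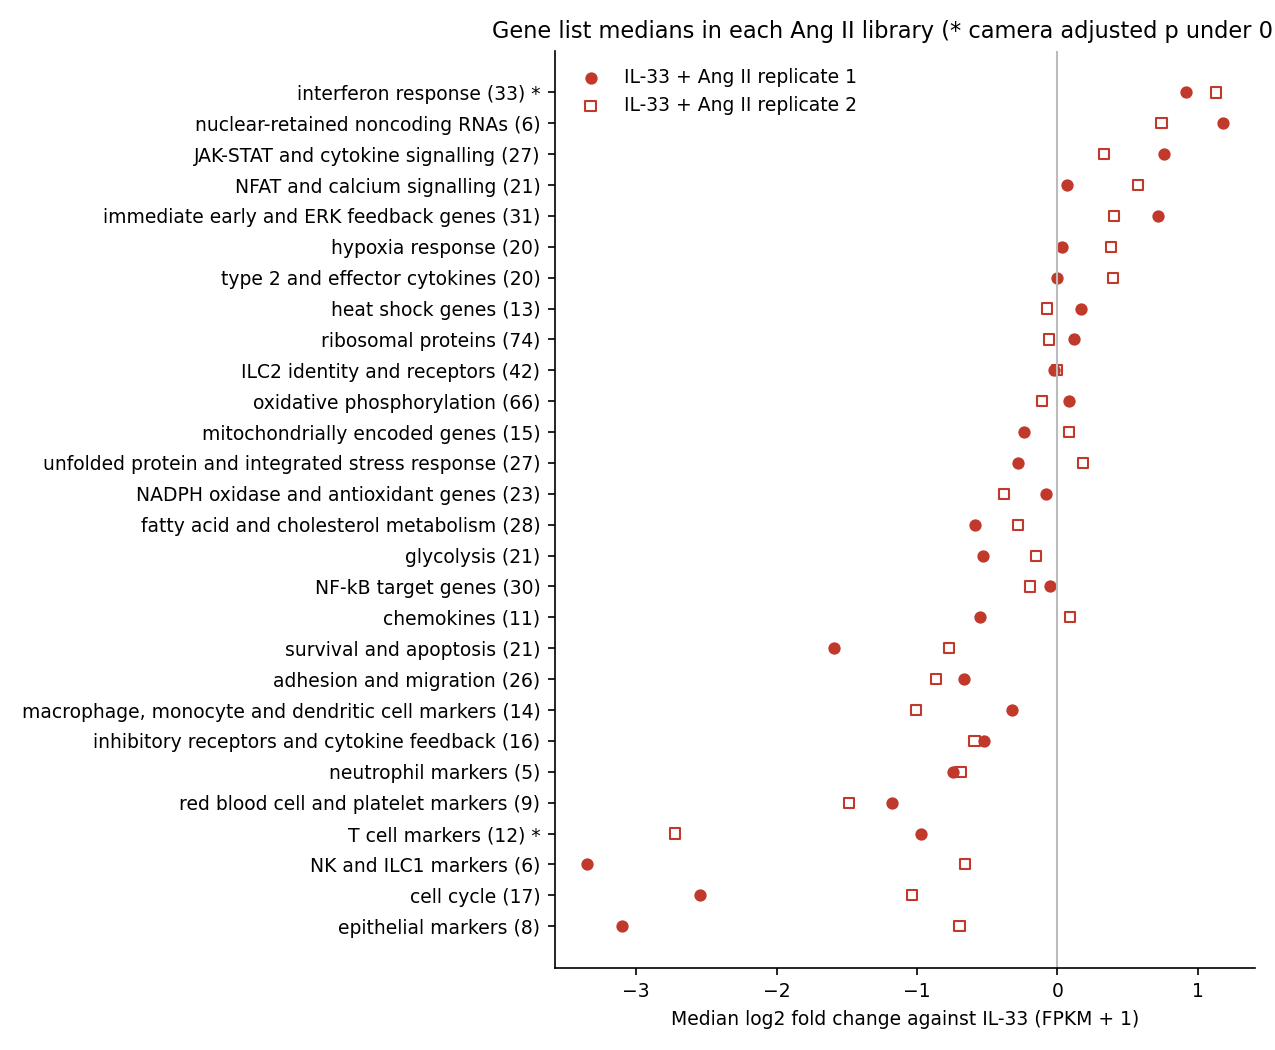
Median log2 fold change of each gene list against IL-33, on the FPKM + 1 scale, in each Ang II library (filled circles, replicate 1; open squares, replicate 2), with the number of measured genes in parentheses and an asterisk where the camera adjusted p was under 0.05. The interferon response list lies at 0.92 and 1.13, and T cell markers lie at -0.97 and -2.72.

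Transcripts of other cell types were also measured, and apart from T cell markers no list of them passed the list test. Each such list that was tested had a median log2 fold change below 0. Of epithelial markers (median -2.35), 1 was higher and 6 lower in both Ang II libraries. For NK and ILC1 markers (-2.01) these counts were 1 and 3. They were 0 and 4 for neutrophil markers (-0.99) and 0 and 5 for red blood cell and platelet markers. Of all tested genes, 24.4% were higher and 33.5% lower in both. Medians of the lists too short to test lay on both sides of 0. Haemoglobin genes took 5.83% and 5.78% of the FPKM sum in the IL-33 libraries and 0.897% and 0.401% in the Ang II libraries. Hba-a2 stood at 9498 FPKM against 1254 and 482 FPKM and Hba-a1 at 8875 against 1115 and 365 FPKM, and these near-identical copies can share reads. The list of red blood cell and platelet markers had a median log2 fold change of -1.33 over 9 genes (camera adjusted p = 0.169). Among genes with a mean of at least 5 FPKM its median was -2.71 (camera adjusted p = 0.0288). Of 14 measured macrophage, monocyte and dendritic cell markers, 4 were higher and 8 lower in both Ang II libraries (camera adjusted p = 0.382). Lyz2 stood at 1684 against 1016 and 683 FPKM, and Chil3 at 211 against 696 and 158 FPKM. Marco was listed at 0 with IL-33 and stood at 191 and 23.2 FPKM with Ang II. The epithelial secretoglobin gene Scgb1a1 stood at 250 against 76.9 and 133 FPKM, and the surfactant gene Sftpc at 81.0 against 3.17 and 43.2 FPKM (8 epithelial genes, camera adjusted p = 0.382). Among 6 NK and ILC1 markers, 4 passed when adjusted over the list alone (camera adjusted p = 0.382). Nkg7 stood at 30.4 FPKM and Klrd1 at 20.3 FPKM with IL-33, each listed at 0 in both Ang II libraries. Fcgr3 stood at 0.445 against 38.7 and 55.5 FPKM, and Gzmb at 18.0 FPKM with 0 listed in one Ang II library and 41.3 FPKM in the other. Il17a was listed at 0 with IL-33 and stood at 37.9 and 16.6 FPKM with Ang II, and Il17f at 0.065 against 48.2 and 30.4 FPKM. Lta, the other measured ILC3 marker, stood at 91.0 against 21.3 and 41.0 FPKM, and with 3 measured genes the list was not tested. Among neutrophil markers (5 genes, camera adjusted p = 0.290), Il1b stood at 124 against 0.26 and 315 FPKM and Clec4d at 128 against 76.3 and 78.6 FPKM. Ribosomal protein genes (74 genes, median 0.05, camera adjusted p = 0.382), mitochondrially encoded genes (15 genes, median -0.06, camera adjusted p = 0.931) and heat shock genes (13 genes, median 0.16, camera adjusted p = 0.618) did not pass the list test. Their most abundant members were Rplp1 (994 against 990 and 712 FPKM), Rpl36 (415 against 1204 and 587 FPKM), mt-Rnr2 (3593 against 4443 and 4157 FPKM), mt-Rnr1 (2687 against 3561 and 3148 FPKM), Hspa8 (622 against 706 and 686 FPKM) and Hsp90ab1 (283 against 318 and 315 FPKM). Lists with under 5 measured genes were not tested. In these, Cd79b of B cells stood at 13.2 against 50.5 and 0.28 FPKM, Ighm at 3.71 against 41.0 and 1.18 FPKM, and the eosinophil gene Ear2 at 54.4 against 0.16 and 33.9 FPKM. Hdc, of mast cells and basophils, stood at 0.10 against 28.4 and 26.04 FPKM, endothelial Cldn5 at 29.4 against 0.05 and 0 FPKM, endothelial Pecam1 at 1.15 against 0.11 and 9.08 FPKM, and fibroblast Col1a1 at 1.42 against 1.26 and 1.23 FPKM.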

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

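Scaling without haemoglobin genes, at least 20 FPKM in every library, and the settings for the similarity of the samples were chosen after seeing the data. So was counting the IL-33 libraries as 1 sample, while counting both as replicates was the fit planned beforehand. The cause of each change was not tested unless stated. With IL-33 as 1 sample, 0 genes passed adjusted p under 0.05 (limma) in either direction with 257 higher and 996 lower at unadjusted p under 0.05, and 0 passed with pseudocounts of 0.1 and 5, other filters on the mean, trimmed mean or quantile scaling, no trend, either IL-33 library left out, or adjusted p under 0.1. With both IL-33 libraries counted, 457 and 1090 genes passed, with 984 and 1598 at unadjusted p under 0.05, and 2 lists rose; the added residual degree of freedom comes from the near-identical IL-33 pair. Among the 1563 genes with at least 20 FPKM in every library, which leaves out genes near 0 in any library, 1 gene was higher (Nr4a1, adjusted p = 0.0141) and 4 lower (Hba-a1, Hba-a2, Hbb-bs and Hbb-bt), with more higher than lower at unadjusted p under 0.05 (53 and 45) and 0 lists lower (T cell markers had under 5 members left). At unadjusted p under 0.05 and at least a 2-fold change, 251 genes were higher and 995 lower. Lower genes at unadjusted p under 0.05 numbered 2341 with no filter (18255 genes tested) and 330 with a mean of at least 5 FPKM (5756 genes tested). The labels do not say that a replicate number marks a shared mouse or day, and a correlation of -0.02 between deviations of same-numbered libraries decides nothing, since the IL-33 libraries hardly deviate; with the replicate number as a block, which needs both IL-33 libraries, 0 genes passed, 618 were higher and 1217 lower at unadjusted p under 0.05, and 2 lists rose. Lists that rose numbered 2 with a mean of at least 5 FPKM and with quantile scaling, and 1 to 2 with an IL-33 library left out (2 without IL-33 replicate 2); the added list was that of immediate early genes. With a mean of at least 5 FPKM the T cell list was lost and the red blood cell list fell (adjusted p = 0.0288). Over the alternatives, the camera or fry adjusted p ran from 4.208e-07 to 0.838 for interferon genes, from 0.00273 to 0.838 for T cell markers and from 0.0288 to 0.838 for immediate early genes. With an estimated correlation 0 lists rose and 0 fell, and with fry likewise 0 and 0. Both tests rest on 1 residual degree of freedom, which leaves little room for any list to pass. With IL-33 as 1 sample, camera with its preset correlation rests on the same fit. Lists pass there under an assumed correlation of 0.01. Quantile scaling moved the median log2 fold change of all genes to 0.17, below the interferon list's 0.94. Leaving out an Ang II library leaves no residual degrees of freedom, so it gives values with no test. In the similarity of the samples, r of the IL-33 pair, the Ang II pair and the lowest and highest between groups was 0.9916, 0.4167, 0.3925 and 0.4256 with a pseudocount of 0.1, 0.9955, 0.7084, 0.6865 and 0.7174 with 5, and 0.9928, 0.835, 0.8151 and 0.8367 at 20 FPKM or more in every library. The Ang II pair's r lay above the highest r between groups in the reported setting and below it in these, and its Spearman's rho lay below in the reported setting too (0.475 against 0.490 to 0.499). Some lists that passed in neither setting changed direction, such as ILC2 identity and NFAT genes, which camera placed higher and fry lower. Depth limits low genes, and single genes at 0 in one library cannot be read as absent.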

Other observations

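The tests of explanations in this part were chosen after the results had been seen. Several gene groups not described above had single genes that were higher or lower in both Ang II libraries, while their lists did not pass camera. In the unfolded protein and integrated stress response list (27 measured genes, 9 higher and 9 lower in both, adjusted p = 0.618), Dnajb9, a chaperone gene of the endoplasmic reticulum, stood at 11.4 FPKM with IL-33 against 195 and 119 FPKM with Ang II. In the JAK-STAT and cytokine signalling list (27 genes, 12 higher and 5 lower, adjusted p = 0.169), Pim1 stood at 0.13 against 31.98 and 19.7 FPKM. In the adhesion and migration list (26 genes, 8 higher and 13 lower, adjusted p = 0.382), Ccr7, which guides lymphocytes to lymph nodes, stood at 81.0 against 0.14 and 0.11 FPKM, and S1pr1, which governs exit from tissue, at 19.6 against 0.18 and 0.10 FPKM. In the survival and apoptosis list (21 genes, 4 higher and 9 lower, adjusted p = 0.470), the pro-apoptotic genes Bid and Pmaip1 stood at 16.6 against 0.04 and 0 FPKM and at 16.3 against 0.04 and 0.08 FPKM, and the anti-apoptotic gene Bcl2l1 at 26.1 against 6.90 and 0.11 FPKM. Genes of glycolysis (21 genes, adjusted p = 0.382), oxidative phosphorylation (66 genes, adjusted p = 0.632), fatty acid and cholesterol metabolism (28 genes, adjusted p = 0.561), hypoxia (20 genes, adjusted p = 0.382) and antioxidant defence with NADPH oxidase (23 genes, 5 higher and 10 lower, adjusted p = 0.774) did not pass either. In the last of these, the catalase gene Cat stood at 47.2 against 0.50 and 2.36 FPKM and the oxidase subunit gene Ncf4 at 91.0 against 349 and 389 FPKM. The lists of inhibitory receptors (16 genes, adjusted p = 0.470) and NFAT and calcium signalling (21 genes, adjusted p = 0.606) did not pass.

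The near identity of the 2 IL-33 libraries beside the distance between the 2 Ang II libraries is the first pattern. One IL-33 library or its amplified cDNA measured 2 times may account for it. Between 1 and 32 (FPKM times kilobases) the IL-33 spread was 0.91 times the counting noise at the IL-33 depth. The spread of the Ang II libraries was 14.1 times that same noise. This explanation stays open, since the IL-33 spread reached 2.54 times that noise in the most abundant genes, more than counting alone gives. That cells of the Ang II samples answered Ang II differently stays open. Genes of oxidative phosphorylation differed between the Ang II libraries 1.29 times as much as the mean of their differences from IL-33. Their median absolute log2 difference was 0.54 against 0.49 and 0.34, and the bootstrap interval, 0.883 to 1.75, lies on both sides of 1. The ratio cannot decide this, since these genes were chosen as ones every cell uses and amplification also makes them differ. The interval resamples genes, not samples.

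The second pattern is the many genes that differ between IL-33 and Ang II, often from present to absent. Transcripts lost at random in libraries made from few cells could account for much of it, since 638 genes set the IL-33 sample apart (at least 10 FPKM against under 1), while 764 and 641 set one Ang II library apart from the other and from IL-33. When an IL-33 library measured 2 times was simulated, a mean of 1261.4 unchanged genes were called with both libraries counted, beside 1547 real calls, so most of these calls could come from counting one library as 2. An effect of Ang II on most of the genes that differ cannot be told apart from this, because 3 samples allow 3 splits, too few for a share under 0.05: IL-33 against Ang II gave 1253 genes at an unadjusted p under 0.05, and the highest of the other splits gave 1395. Single genes such as Il9 and Gal, at 967 FPKM or more in both Ang II libraries, remain candidates for a new measurement.

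The third pattern is the interferon response list. Its median log2 fold change of 0.97 lay above 100% of 10000 random lists of the same size matched on mean expression. The central 95% of these lay between -0.39 and 0.33. The list was taken up because it passed camera on these same fold changes, so the comparison is not separate support. It speaks only against transcripts lost at random one by one, not against losses that members share. More macrophages or monocytes in the Ang II libraries stay open. The 5 most abundant markers measured had a median log2 fold change of 0.13. Against the IL-33 mean, 2 of 5 were higher in both Ang II libraries. Of these, Cd74 stood at 165 against 166 and 196.5 FPKM. Lyz2 and Fcer1g were lower (1684 against 1016 and 683 FPKM, and 335 against 201 and 190 FPKM). The whole list of 14 had a median of -0.82. Of the 14, 4 were higher and 8 lower in both, here outside both IL-33 values. Members go both ways. Purification does not decide it, since markers such as Lyz2 were measured in both groups. That 1 unusual IL-33 library sets the difference cannot be told apart from an effect of Ang II, because the IL-33 libraries were counted as 1 sample. An effect of Ang II on these genes is therefore an untested hypothesis.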
